A study of Mus musculus with 48 samples.

How the data were processed

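Total RNA of hypothalamus, pituitary and the number 4 mammary gland of lactating ICR mice was sequenced by the authors, 8 libraries per treatment and tissue, grouped by the labels' titles. The authors deposited FPKM, 1 value per gene and library; reads were aligned with HISAT2 2.0.5, counted with featureCounts 1.5.0-p3 and tested with DESeq2 1.16.1, per the submitters' processing notes, which do not state how reads aligning to more than 1 place were treated. The labels name the mouse build mm9, whereas gene lengths of GENCODE M21 account for the deposited FPKM, so no coordinates are given. The FPKM were already scaled between libraries: the median ratio to the geometric mean over 13815 genes was 1.0123 in each of the 48 libraries. With these lengths 94.7 to 97.0% of values under 50 fragments came out whole within 0.02 fragments, which gave the denominators and depths. In a gene of 1 kb, 3 fragments corresponded to 0.105 to 0.143 FPKM in hypothalamus, 0.11 to 0.167 in pituitary and 0.322 to 0.6 in mammary gland. These floors cover counting error only. Of 58913 genes 53360 had a symbol in the reference tables; 5448 were loci of the authors outside the reference annotation, which were tested but not named. No pair of libraries held identical values.

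Within each tissue the libraries were divided by their median ratio to the geometric mean (factors 0.970 to 1.017), genes with mean FPKM of at least 1 were kept, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend), 8 heat against 8 control libraries, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels call the libraries biological replicates and say that the tissues came from dams. The heat by tissue interaction was a limma F test over all 48 libraries. Gene lists of processes and cell type markers, fixed before the data were examined together with the tests, the rule for naming genes and the first set of alternatives, were tested with limma's camera at a preset correlation of 0.01, with estimated correlation and fry as alternatives, for lists with at least 5 tested members, or 4 for lists under 8 genes. The shares of summed FPKM held by milk, hormone and neuropeptide genes, and that of mitochondrially encoded genes, were compared by exact permutation over 12870 splits. Overlaps between tissues were tested with Fisher's exact test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

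Genes were named by rule: per tissue the 6 largest rises and 6 largest falls past the threshold, leaving out unnamed and predicted genes, pseudogenes and receptor segments; from each focus list the 2 members past the threshold with the largest change, or, where none passed, the 1 of smallest adjusted p; a fixed set of heat shock, cold-inducible, peptide, hormone and milk genes; from each other list that passed, the 2 members of smallest adjusted p; and the 10 genes shared by all 3 tissues with the smallest largest adjusted p. Of the genes this rule names, 1 is not reported here. Alternatives were the FPKM as deposited, quantile normalization, pseudocounts of 0.1 and 0.5, no filter, a filter of 5, array weights, a robust prior, an exact Wilcoxon test, the replicate number as a block, each library left out, all 48 libraries in 1 fit and a minimum absolute log2 change of 1. After the data were seen, a term for libraries numbered 1 to 3 against 4 to 8, each set alone, marker scores for lobe and lymphocytes, and limma-voom on the recovered fragments were added. On simulated data with the spread of the real genes and 200 changed genes per tissue, changes of 1 log2 unit were recovered for 95.5% of genes in hypothalamus (13957 genes), 92.5% in pituitary (14095) and 82.1% in mammary gland (12587), and changes of 0.5 for 56.1, 51.5 and 42.4%. The false share among calls was 4.5, 6.4 and 2%. The simulated noise was independent between genes, without the shared differences between the real libraries, so these percentages are not error rates of the real calls.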

Results

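Gene expression was measured by RNA sequencing in lactating ICR mice, an outbred laboratory strain, at day 13 of lactation. Dams of 10 weeks were kept at 25 °C or at 36 °C, both at 55% relative humidity, and were killed directly after the treatment, whose duration the labels do not state. Hypothalamus, pituitary and mammary gland were each represented by 8 control and 8 heat libraries, 48 in all. The values were FPKM, fragments scaled to gene length and to a denominator per library, for 58913 genes. That denominator did not follow library depth, and the deposited values were already scaled between the 48 libraries. Fragments on annotated genes, recovered from the FPKM steps, were 16272700 to 22166100 per hypothalamus library, 10893100 to 17246500 per pituitary library and 11586400 to 17809300 per mammary library. Control and heat means were 19242800 ± 1288800 and 18670700 ± 1889100 in hypothalamus, 14758100 ± 1256600 and 14235000 ± 2387100 in pituitary and 14399000 ± 1038000 and 14604100 ± 1910600 in mammary gland (SD, n = 8). Fold changes below are on the log2(FPKM + 1) scale, heat minus control, with the standard error, and understate the change of genes near 1 FPKM. Adjusted p values are from limma. Each named gene past the threshold had 8 of 8 heat libraries on 1 side of the control median, except Per2 and Pck1 (7 of 8), Mir143 (7 of 8) and Mvk (6 of 8) in mammary gland. The threshold was applied to these same libraries, which favours such counts, so they are no separate support for the calls. The number of gene lists past the threshold was matched by 46, 46 and 55 of 100 splits of the libraries in hypothalamus, pituitary and mammary gland; lists are described by their called members.

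The first comparison asked which genes of the hypothalamus, the brain region that controls body temperature and feeding, differed after heat. Heat shock genes rose most. Hspa1b (ENSMUSG00000090877), an inducible HSP70 chaperone, went from 4.86 ± 1.65 to 44.1 ± 29.0 FPKM (SD, n = 8), a log2 change of 2.71 ± 0.34 with adjusted p = 0.00118. Within libraries numbered 1 to 3 the change was 2.29 and within 4 to 8 it was 2.97. Its neighbouring paralog Hspa1a (ENSMUSG00000091971) changed by 2.19 ± 0.36 with adjusted p = 0.00797. These paralogs are nearly identical, so the division of fragments between them is uncertain, and 19.0% of the Hspa1a exon bases are shared with an antisense gene. The small heat shock protein gene Hspb1 rose by 1.93 and the HSP40 gene Dnajb1 by 1.67, each in 8 of 8 heat libraries above the control median. Of 24 genes in the list of heat shock and chaperone genes, 14 rose and 0 fell, and 22 rose when adjusted over the list alone. The list test gave adjusted p = 5.45e-45, and adjusted p = 0.00444 with an estimated correlation. Among cold-inducible RNA-binding genes, Cirbp fell from 35.5 ± 5.01 to 25.4 ± 2.51 FPKM (SD, n = 8; log2 change −0.46, adjusted p = 0.0168), by 0.16 within numbers 1 to 3 and 0.64 within 4 to 8. Rbm3 was 5.87 ± 1.39 in control and 6.45 ± 1.52 in heat (SD, n = 8), with adjusted p = 0.999.

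Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, included Fos, which went from 3.2 ± 0.79 to 13.3 ± 12.4 FPKM (SD, n = 8; log2 change 1.47, adjusted p = 0.0424), and Egr1, with a log2 change of 1.18 and adjusted p = 0.0238. With 1 library left out, the Fos call was lost in 12 of 16 fits and the Egr1 call in 4. In this list 3 of 17 genes rose and 0 fell, with 10 adjusted over the list alone and adjusted p = 0.159 with an estimated correlation. Glucocorticoid targets held 3 risen genes of 19 and 0 fallen, 13 adjusted over the list alone. Zbtb16 rose by 0.77 ± 0.12 (adjusted p = 0.00515) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 0.38 ± 0.08 (adjusted p = 0.0483, lost in 13 of 16 leave-one-out fits). The list had adjusted p = 0.0106 with an estimated correlation. Of 18 clock genes 2 rose, Per2 by 0.56 and Cry1 by 0.35 (lost in 5 and 8 leave-one-out fits), 8 adjusted over the list alone, and the list had adjusted p = 0.00994 with an estimated correlation. In the unfolded protein list 2 of 19 genes rose, Herpud1 by 0.50 and Atf4 by 0.39 (Atf4 lost in 13 leave-one-out fits), 7 adjusted over the list alone, with adjusted p = 0.199 with an estimated correlation. The p53 and apoptosis list held 1 risen gene of 16, Mcl1 (0.35, lost in 12 leave-one-out fits), with 6 higher and 1 lower adjusted over the list alone and adjusted p = 0.106 with an estimated correlation; Cdkn1a had a log2 change of 0.47 with adjusted p = 0.157, and 0.0443 with a term for libraries numbered 1 to 3 against 4 to 8.

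Of 26 neuropeptide genes tested only Npy, which encodes the feeding peptide neuropeptide Y, passed: 69.5 ± 15.8 FPKM in control and 112 ± 18.6 in heat (SD, n = 8; log2 change 0.69, adjusted p = 0.0238). The change was 0.61 within numbers 1 to 3 and 0.74 within 4 to 8, and the call was lost without control replicates 5, 7 or 8 or heat replicates 1 or 5, with adjusted p up to 0.0582. Agrp, made by the same neurons, had a log2 change of 0.48 with adjusted p = 0.472. Trh, Crh, Oxt and Avp had log2 changes of 0.05, −0.27, −0.06 and 0.33, none past the threshold. Neuropeptide genes held 1.34 ± 0.32% of summed FPKM in control and 1.43 ± 0.36% in heat (SD, n = 8; exact permutation p = 0.584, 2-sided, 0.7004 adjusted over 6 shares). In the thyroid list Dio2, the enzyme that activates thyroid hormone, had a log2 change of 0.62 with adjusted p = 0.167. Among fallen genes were Opalin, an oligodendrocyte gene (−0.69, lost in 6 leave-one-out fits), Heyl (−0.46), Lcmt2 (−0.45), Fam214a (−0.40) and Pskh1 (−0.38). Opalin was the 1 fallen gene of 10 oligodendrocyte markers, a list with adjusted p = 0.00872 by the preset and 0.566 with an estimated correlation; Cnp had −0.24 with adjusted p = 0.553. Mir7048 rose by 1.41 (lost in 10 leave-one-out fits) from a control mean of 0.418 FPKM, below the 1.82 FPKM or more of 3 fragments in its 58 bases, and it lies within Dedd2, a death effector domain gene that is on the heat shock list and rose, and fragments of the host cannot be separated from it. In all 95 genes passed of 13957 tested, 78 higher and 17 lower. Libraries numbered 1 to 3 stood apart from those numbered 4 to 8 in either treatment; a term for this difference gave 486 genes. In 1 fit of all 48 libraries, which shares the spread of the tissues, 59 genes passed, 30 higher and 29 lower, 28 of them among the 95, and 13 of the named calls ended. These were Zbtb16 (adjusted p = 0.431), Cirbp (0.238), Fam214a (0.117), Npy (0.0854), Herpud1 (0.0763), Fos, Egr1, Tsc22d3, Per2, Cry1, Atf4, Mcl1 and Mir7048 (0.0926 to 0.915). The 95 genes had the same sign within numbers 1 to 3 and within numbers 4 to 8. They were selected on both sets together, which favours this, so it is no separate support for the calls. The 3 against 3 fit alone called 0 with limma, with 963 genes at an unadjusted p under 0.05.

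**Figure D1:**
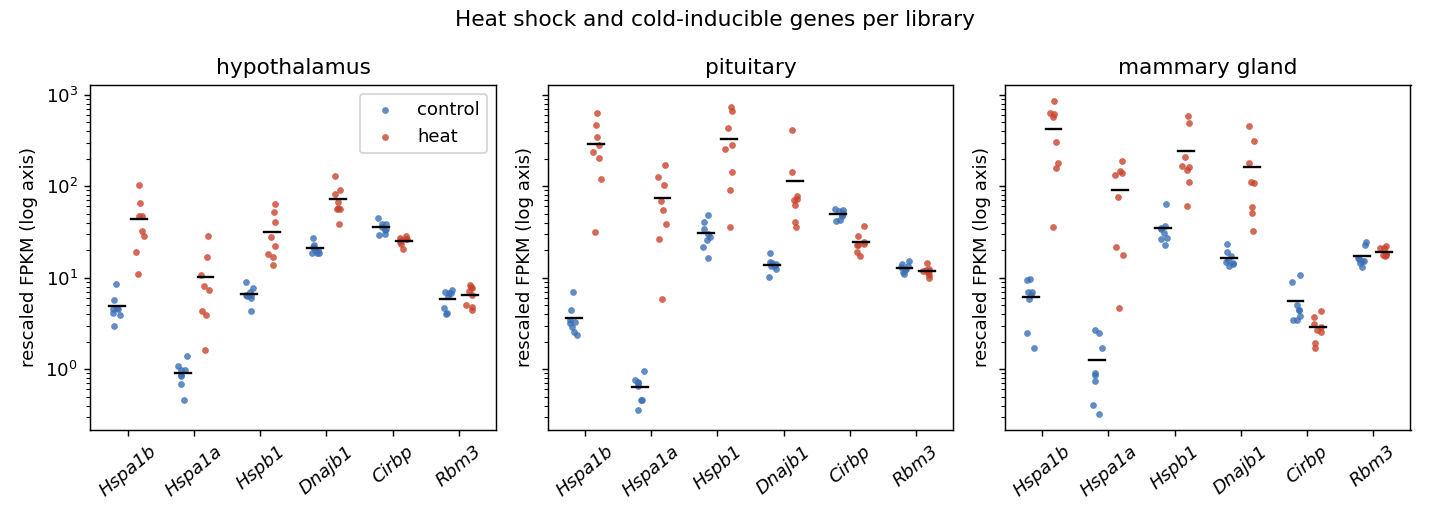
Rescaled FPKM on a log axis of 6 genes in each tissue, 1 point per library, control in blue and heat in red, with the group mean as a black bar. Hspa1b in heat averaged 44.1 FPKM in hypothalamus, 288 in pituitary and 418 in mammary gland, against 4.86, 3.65 and 6.19 in control. Levels are not ranked between tissues, since the FPKM denominator did not follow library depth.

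In the pituitary, the gland that hypothalamic signals control, heat shock genes rose as well. Hspa1b went from 3.65 ± 1.52 to 288 ± 190 FPKM (SD, n = 8), a log2 change of 5.61 ± 0.45 with adjusted p = 8.01e-06, and Hspa1a changed by 5.04 ± 0.48. Hspb1, Dnajb1 and Hsph1, an HSP110 chaperone gene, rose by 2.92, 2.51 and 2.30. Of the 24 listed heat shock and chaperone genes 22 rose and 0 fell, 23 adjusted over the list alone. The list had adjusted p = 2.58e-39 by the preset and adjusted p = 0.107 with an estimated correlation. Cirbp fell from 49.4 ± 5.49 to 24.3 ± 5.89 FPKM (SD, n = 8; log2 change −1.02, adjusted p = 0.000248) and the splicing factor gene Srsf5 fell by 0.63. These were the 2 fallen of 7 cold-inducible genes, 4 adjusted over the list alone with 2 risen there, and adjusted p = 0.528 with an estimated correlation. Rbm3 had a log2 change of −0.12 with adjusted p = 0.489.

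Prl, the prolactin gene, fell from 22.4 ± 11.2 to 6.23 ± 5.49 FPKM (SD, n = 8; log2 change −1.90 ± 0.41, adjusted p = 0.0153), in 8 of 8 heat libraries below the control median. Its level ranked far below that of Pomc, the precursor gene of ACTH and melanocortins, at 27410 ± 14570 and 50810 ± 32870 FPKM (SD, n = 8), and why was not found. No exon base of Prl is shared with another gene of the reference annotation. Overlap with the authors' own loci was not tested, and how fragments that align to more than 1 place were counted is not stated. Gh, growth hormone, was likewise low, at 11.2 ± 6.28 and 14.2 ± 9.46 FPKM (SD, n = 8; adjusted p = 0.854). Pomc had a log2 change of 0.87 with adjusted p = 0.534 and Tshb −0.12 with adjusted p = 0.836. With a score of neurointermediate lobe markers and the library set in the model the change of Pomc was 0.18, and that of Prl −1.64 with adjusted p = 0.00381. Control replicate 1 and heat replicate 3 stood apart in this score, at −2.69 and −1.82, and without both the changes were 0.76 for Pomc (adjusted p = 0.283) and −1.99 for Prl (0.00567). Within numbers 1 to 3 and 4 to 8 the Prl change was −1.60 and −2.07. Hormone genes together, of whose FPKM Pomc made up nearly all, held 14.04 ± 6.53% of summed FPKM in control and 21.3 ± 11.4% in heat (SD, n = 8; exact permutation p = 0.142, 2-sided, 0.425 adjusted over 6 shares). Prl was the 1 fallen of 7 hormone genes, 2 adjusted over the list alone. Other large falls were Nog, the BMP antagonist noggin (−1.57 ± 0.21), Lrrc10b (−1.04) and Rasd1 (−0.95). Isl1, a pituitary transcription factor gene, fell by 0.34.

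Glucocorticoid targets held 3 risen genes of 20 and 0 fallen, 5 adjusted over the list alone, led by Pdk4 (0.74 ± 0.14) and Ddit4 (0.67 ± 0.11), with adjusted p = 0.431 with an estimated correlation. Jun was the 1 risen of 18 immediate early genes (1.11, adjusted p = 0.02), and that list did not pass its test. Per2 had a log2 change of 0.82 with adjusted p = 0.124 and Herpud1 0.36 with adjusted p = 0.0938; with the library set as a term these were 0.0134 and 0.0453. Cholesterol synthesis genes passed the list test as lower (adjusted p = 0.00272; 0.528 with an estimated correlation), though 0 of 19 passed alone; Sqle had −0.29 with adjusted p = 0.14, and 0.0189 with the set term. Of 11 genes of lactose and glucose supply 1 fell, Galk1 by 0.41, 3 adjusted over the list alone (0.431 with an estimated correlation), and Pgm2 had −0.24 with adjusted p = 0.112, and 0.00678 with the set term. Of 5 proliferation genes 1 fell, Mcm3 by 0.31 (lost in 6 leave-one-out fits; list 0.431 with an estimated correlation), and Cdc20 had −0.38. Mir7048, with a control mean of 0.588 FPKM also below the level of 3 fragments, rose by 1.98 within risen Dedd2, and Rnu73b, inside Rps3a1, fell by 0.97. In 1 fit of all 48 libraries the calls of Ddit4, Jun, Mcm3 and Rnu73b ended, at adjusted p of 0.0647 to 0.274. In all 534 of 14095 genes passed, 334 higher and 200 lower, and 1721 with the library set as a term. The 534 kept their sign within both sets, which selection on both together favours. The 3 against 3 fit called 0 with limma, with 1588 genes at an unadjusted p under 0.05. Higher genes were 62.5% of calls, and 54.9% with FPKM as deposited.

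**Figure D2:**
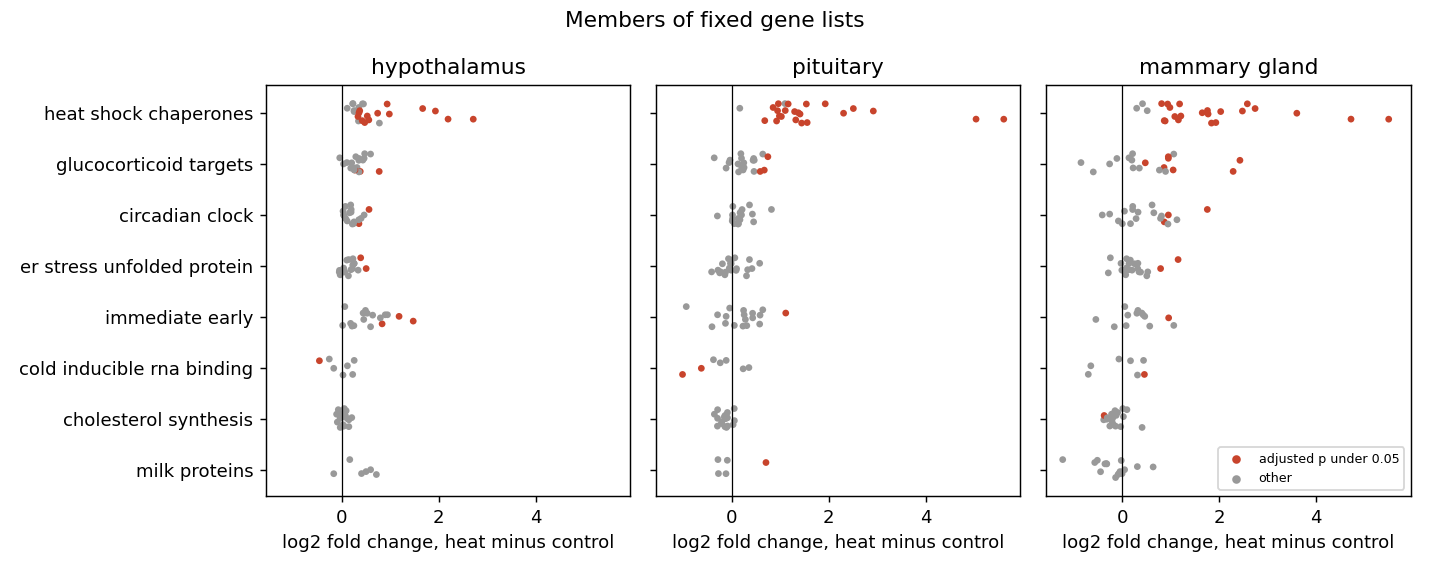
Log2 fold change, heat minus control, of each tested member of 8 fixed lists in each tissue, red where adjusted p was under 0.05. Heat shock and chaperone genes lie to the right, with 14, 22 and 21 of 24 risen in hypothalamus, pituitary and mammary gland, while 0 of 16 milk protein genes passed in mammary gland.

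In the mammary gland, taken at peak lactation, Hspa1b went from 6.19 ± 2.89 to 418 ± 290 FPKM (SD, n = 8; log2 change 5.50 ± 0.54, adjusted p = 5.02e-05). Hspa1a, Hsph1, Dnajb1, Hsp90aa1 and Hspb1 rose by 4.72, 3.61, 2.75, 2.58 and 2.48. Of the 24 listed heat shock and chaperone genes 21 rose and 0 fell, 24 adjusted over the list alone, with adjusted p = 1.39e-31 by the preset and adjusted p = 0.122 with an estimated correlation. Cirbp had a log2 change of −0.70 with adjusted p = 0.059 and Rbm3 0.17 with adjusted p = 0.411, while Clk4, a splicing kinase gene, rose by 0.46 (lost in 12 leave-one-out fits).

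Of 16 milk protein genes 0 passed with limma, and 2 were lower with the library set as a term, Lalba and Trf, the latter named after its values were seen. Csn2, the β-casein gene, was at 73740 ± 13230 FPKM in control and 70090 ± 8961 in heat (SD, n = 8; log2 change −0.06 ± 0.13, adjusted p = 0.836) and Csn1s1 at 46320 ± 11930 and 44020 ± 5874 (SD, n = 8; adjusted p = 0.913). Lalba, the α-lactalbumin gene needed for lactose, had −0.51 with adjusted p = 0.165, and 0.0445 with the set term, and Wap −1.23 with adjusted p = 0.0802; the Wap level, 80.7 FPKM in control, lay far below the caseins, and why was not found. Milk protein genes held 52.0 ± 4.34% of summed FPKM in control and 50.4 ± 2.19% in heat, a difference of −1.69 points (SD, n = 8; exact permutation p = 0.338, 2-sided, 0.507 adjusted over 6 shares). Within numbers 1 to 3 the difference was −3.98 points and within 4 to 8 −0.32. In lipid synthesis 1 of 27 genes fell, Gpam by 0.47, and in cholesterol synthesis 1 of 21, Mvk by 0.37 (lost in 12 leave-one-out fits; list adjusted p = 0.0378; 0.721 with an estimated correlation). Slc1a5, a glutamine transporter gene, rose by 0.52 (lost in 11 leave-one-out fits). Elf5 had −0.27 with adjusted p = 0.161 and Bcl2l11 0.29 with adjusted p = 0.127.

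Glucocorticoid targets rose in 7 of 19 cases with 0 fallen, 9 adjusted over the list alone (0.122 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, went from 38.0 ± 26.3 to 192 ± 93.3 FPKM (SD, n = 8; log2 change 2.43, adjusted p = 0.0015) and Tsc22d3 from 20.1 ± 8.08 to 100.2 ± 34.7 (SD, n = 8; log2 change 2.29, adjusted p = 0.000152). Of 19 clock genes 3 rose, among them Per2 by 1.76 and Nr1d1 by 0.87, with 9 higher and 1 lower adjusted over the list alone (0.305 with an estimated correlation). Herpud1 and Ddit3 rose, with ratios of mean FPKM of 2.41 and 1.88, the 2 risen of 21 unfolded protein genes, 4 adjusted over the list alone (0.721 with an estimated correlation). Among adipocyte markers 1 of 11 rose, Pck1 by 1.26 (0.721 with an estimated correlation), and Pnpla2 had 0.39. Of 76 ribosomal protein genes 0 passed, though the list did (adjusted p = 0.0032; 0.721 with an estimated correlation); Rps9 and Rpl29 had 0.24 and 0.48. T cell markers passed as a list (adjusted p = 0.0312, and 0.721 with an estimated correlation), but in only 9 of 16 leave-one-out fits and with 0 of 8 genes passed. Lck and Cd4 had 1.51 and 1.14, with 0.03 and −0.17 within numbers 1 to 3 and 2.40 and 1.93 within 4 to 8. T cell genes were high in control library 5 and heat libraries 4, 5, 6 and 8. Large falls were those of the potassium channel gene Kcnk5 (−1.33 ± 0.20), Olfr279 (−1.26) and Cmtm2a (−1.23). Mir6993, within Fads1, Mir143, and Mir6386, within Plscr1, also passed as lower (−2.34, −2.31 and −1.50). They span 65, 63 and 104 bases, so 3 fragments correspond to at least 4.96, 5.12 and 3.1 FPKM, and their heat means of 2.46, 1.34 and 1.54 FPKM lay below that; the sizes of these falls cannot be ranked at this depth. Cmtm2a shares 44.7% of its exon bases with other genes. Mir143, Mir6386 and Cmtm2a lost their calls in 13, 8 and 5 of 16 leave-one-out fits. In all 668 of 12587 genes passed, 357 higher and 311 lower, and 919 with the library set as a term. With a lymphocyte score besides 345 passed, and only 284 of these were among the 668. The comparisons across tissues were not run with this score. The 668 kept their sign in both sets, which selection on both together favours. The 3 against 3 fit called 0 with limma, with 1564 genes at an unadjusted p under 0.05. With the replicate number as a block the calls of Pck1 and Mvk ended (adjusted p = 0.0508 and 0.0637). The exact Wilcoxon test ended those of Mir6993, Mir143, Mir6386, Cmtm2a, Clk4, Gpam, Mvk, Nr1d1 and Pck1, at 0.0556 to 0.151. With the set and lymphocyte score in the model the calls of Per2, Pck1, Gpam, Mvk, Clk4, Mir143, Mir6386 and Cmtm2a ended, at adjusted p of 0.0545 to 0.174; the change of Per2 was then 1.64 and that of Mvk −0.21.

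**Figure D3:**
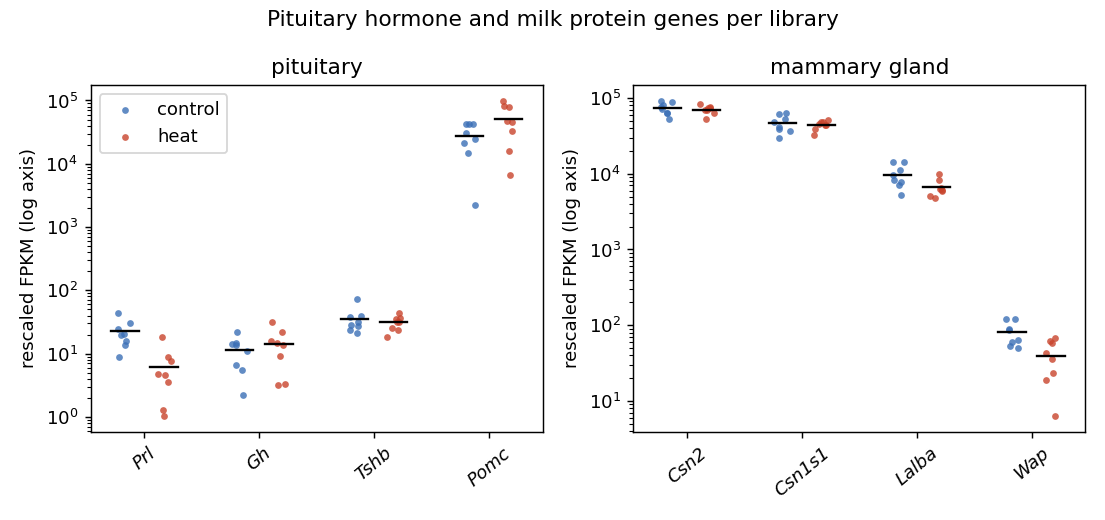
Rescaled FPKM on a log axis of 4 hormone genes in pituitary and 4 milk protein genes in mammary gland, 1 point per library, with group means as black bars. Prl averaged 22.4 in control and 6.23 in heat, and Csn2 73740 and 70090.

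Across tissues, 26 genes passed in all 3 in the same direction, 24 higher and 2 lower, of 9681 tested in each; 0.05 and 0.0033 would be shared by independent lists. The 10 whose largest adjusted p over the tissues was smallest were Hspa1b, Dnajb1, Ccdc117, Dnaja4, Gm15542, Hspb1, P4ha1, Hsph1, Hspa1a and Serpinh1. Pituitary and mammary gland shared 93 higher genes where 7.79 were expected and 31 lower where 2.86 were expected, while 34 and 3 were shared by hypothalamus and pituitary, and 35 and 5 by hypothalamus and mammary gland. Across genes, which are not independent replicates, log2 changes correlated at 0.50, 0.46 and 0.52. Same-numbered libraries of 1 treatment resembled each other across tissues. Differences between control and heat libraries that heat did not cause could therefore recur in each tissue. The expected overlaps and the correlations take no account of this, and for pairs of tissues neither was set against other splits of the libraries. The heat change itself differed between tissues for 174 of 9681 genes in a fit that takes the 48 libraries as independent, for 548 with the number within a treatment as a block across tissues and for 679 with the set term. The mammary change differed from the hypothalamic for 129 genes, from the pituitary for 163, and the pituitary from the hypothalamic for 2. With the set term these were 465, 613 and 6. These contrasts share 1 spread per gene over the tissues. Such sharing moved the calls within hypothalamus, pituitary and mammary gland from 95, 534 and 668 to 59, 815 and 2311. The 3 counts are therefore not ranked. Hspa1b, with 2.71 in hypothalamus and 5.61 in pituitary, was not among the 2. Tsc22d3 rose more in mammary gland than in hypothalamus, by 1.91 ± 0.25 (adjusted p = 7.81e-06), and Ddit4 by 2.08 ± 0.34. Hsph1 exceeded the hypothalamic change by 2.87 ± 0.47 in mammary gland. Rasd1 fell in pituitary and rose in mammary gland, a difference of 2.41 ± 0.39 (adjusted p = 0.000148). The Cirbp change was not shown to differ (adjusted p = 0.367). Of 21, 19 and 23 named calls in hypothalamus, pituitary and mammary gland, 4, 4 and 3 had a log2 change over 2 times as large in 1 library set as in the other, a limit chosen after the data were seen. These were Mir7048, Opalin, Cirbp and Pskh1 in hypothalamus, Rnu73b, Isl1, Ddit4 and Mcm3 in pituitary, and Kcnk5, Cmtm2a and Mvk in mammary gland; whether the change differs between sets was not tested.

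**Figure D4:**
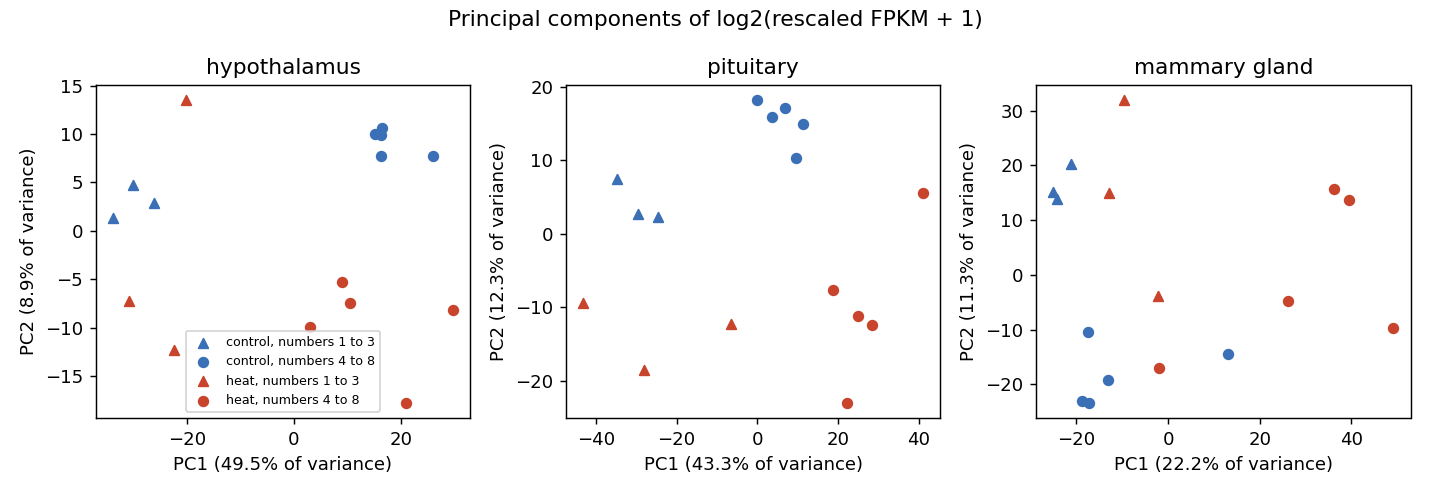
First and second principal components of log2 expression in each tissue, triangles for libraries numbered 1 to 3 and circles for 4 to 8, blue for control and red for heat. The first component held 49.5% of the variance in hypothalamus, 43.3% in pituitary and 22.2% in mammary gland.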

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

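The tests of other splits, of a shared batch, of gene length, of overlapping genes and of chance lymphocyte content were stated before their results were seen; the tests of whether the library sets make the heat calls, of the sets within each treatment and of lymph node tissue were chosen after the result was seen, as was the demand that the lymph node correlation hold without its 2 farthest libraries.

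In 190 groups of 8 libraries of a named gene, 16 held a library far from the others, by Dixon's 95% limit on its gap to the nearest other over the range. The gap was taken on log2(rescaled FPKM + 1), so the FPKM given below do not yield it directly, and another scale could flag other libraries. Chance gives about 1 in 20, or 9.5. In hypothalamus these were Egr1 in control replicate 1 (2.659 FPKM, others from 3.801) and heat replicate 4 (31.35, others to 11.99), Trh in heat replicate 2 (167.3, others to 70.52) and Tsc22d3 in heat replicate 6 (25.34, others to 19.42). In pituitary they were Ddit4 in heat replicate 4 (91.39, others to 63.19), Lrrc10b in control replicate 1 (55.63, others to 45.92) and Pomc in control replicate 1 (2206, others from 14550). In mammary gland control replicate 5 stood out for Cd4 (5.507, others to 0.5233) and Lck (11.84, others to 0.3709). Control replicate 6 stood out for Hsp90aa1 (111.0, others to 73.36) and Hspb1 (64.24, others to 36.55), and control replicate 4 for Cmtm2a (0.08541, others from 2.537). Heat replicate 7 stood out for Cmtm2a (2.436, others to 0.7114). Heat replicate 3 stood out for Herpud1 (13.96, others from 27.7), Per2 (3.996, others from 14.5) and Mir143 (8.951, others to 1.748).

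Of 45 named genes tested for a heat change that differs between tissues, 10 passed by the limma F test. Tsc22d3 (adjusted p = 1.81e-06), Ddit4 (0.000138) and Herpud1 (0.0204) had their largest change in mammary gland. Hsph1 (0.00048), Hsp90aa1 (0.00338), Hspa1b (0.00981) and Hspa1a (0.0376) had their smallest change in hypothalamus. Lcmt2 (0.000168) had its lowest change in mammary gland, and Rasd1 (0.00052) fell in pituitary and rose in mammary gland. Mir6993 (0.0175) also passed, but its heat mean in mammary gland lay below the level of 3 fragments, so its changes are not ranked across tissues.

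Chance is argued against for the gene counts: of 100 splits of the libraries, the real one included, only 1, the real one, gave as many genes in each tissue. A share under 1 in 100 cannot be reached with 100 splits, so chance is not excluded beyond that. The real counts were 95, 534 and 668 in hypothalamus, pituitary and mammary gland, and the highest others 3, 2 and 2. With splits within the library sets and a term for the set, the real counts were 486, 1721 and 919 and the highest others 2, 1 and 131. The interaction gave 174 against 71 and the genes shared by all 3 tissues 26 against 0. Chance could not be excluded for the number of lists past the threshold: 46, 46 and 55 of 100 splits gave at least the real 7, 6 and 8, with up to 19, 14 and 18.

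Libraries numbered 1 to 3 stood apart from those numbered 4 to 8 on the first principal component in hypothalamus and pituitary within each treatment, and on the second in control mammary gland. The heat mammary libraries did not split this way: replicate 7 lay beside replicate 2, and replicates 4, 5, 6 and 8 were those high in T cell genes. Gene length as a cause common to the tissues is argued against, since the Spearman correlation of the difference with length was −0.011 in mammary gland, 0.045 in hypothalamus and 0.24 in pituitary. Each set held control and heat libraries in equal numbers, so by design a set difference alike in both treatments could not make the heat calls. Libraries numbered 4 to 8 alone, where the set difference cannot enter, gave 454, 1399 and 364 genes in hypothalamus, pituitary and mammary gland. Given that balance, these counts are no separate evidence on the question. A handling or sequencing batch shared by the tissues stays open and is consistent with correlations of the difference across genes of at least 0.522 between tissues. In control alone they were at least 0.668, and in heat alone 0.599 between hypothalamus and pituitary but 0.37 and 0.239 with mammary gland, so in heat mammary gland it is less clear. Different cohorts of dams could give the same and were not tested.

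T cell markers had positive changes in the heat mammary gland as a list, with 0 of 8 past the threshold by limma. The lymphocyte score was 1.43 ± 0.81 in control and 2.35 ± 1.25 in heat (SD, n = 8; exact permutation p = 0.101, 2-sided), so uneven lymph node content by chance stays open. Lymph node tissue in some samples may be the source: T cell and lymph node stroma scores correlated at r = 0.837 in control (exact permutation p = 0.0682, rho 0.262) and 0.988 in heat (exact permutation p = 0.0021, rho 0.905, n = 8 each). Without the 2 farthest libraries of each treatment the values were −0.286 in control and 0.984 in heat, so the correlation was not seen among the other control libraries, and the libraries fall into high and low clusters too small for a correlation within them. Lymph node tissue therefore cannot be told apart from lymphocytes entering the gland, which the design leaves untested.

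Prl, Gh, Wap and Glycam1 lay far below the most abundant genes of their tissue. Fragments left uncounted because of an overlapping gene of the reference annotation are argued against, since 0.0% of their exon bases are shared with another such gene. The 5448 loci of the authors outside that annotation were not part of this test, so overlap with them stays open. How fragments that align to more than 1 place were treated is not stated and stays open, so what these FPKM, and the fall of Prl, leave out is unknown. No biological explanation was tested.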

How the results depend on the processing

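The terms for the library set, each set alone, the lobe and lymphocyte scores, the fit without 2 pituitary libraries and the fit on recovered fragments were chosen after the data were seen. No named gene reversed direction past its threshold under any alternative run. The alternatives fixed in advance, apart from 2 kinds, ended a named call in 29, 6 and 23 cases in hypothalamus, pituitary and mammary gland. They left 289, 299 and 354 on their side of the threshold, which includes named genes that were not called and stayed so. In 3, 8 and 12 cases they brought a named gene past it. The kinds left out were leave-one-out fits and the minimum log2 change of 1, which was not scored per named gene. Named genes removed by the filter of 5 were not counted for that setting, so the cases ended are a lower limit. All 48 libraries in 1 fit ended 13, 4 and 0 named calls, no filter 10, 2 and 8, and the exact Wilcoxon test 3, 0 and 9. Counts of genes stayed within 1.5 times of 95, 534 and 668 in hypothalamus, pituitary and mammary gland with FPKM as deposited, quantile normalization, pseudocounts of 0.1 and 0.5, a robust prior, the exact Wilcoxon test and recovered fragments (77 to 105, 465 to 557 and 539 to 731). The share of higher calls in pituitary was 62.5%, and 54.9% and 54.4% with FPKM as deposited and quantile normalization; in mammary gland it was 53.4%, 50.2% and 48.3%. Without a filter, which tests more genes, hypothalamus had 61 and mammary gland 411; a filter of 5, which tests fewer, gave 57, 214 and 364, and 57 for the interaction against 174. Array weights gave 1160, 1398 and, for the interaction, 1060; the cause was not tested. The set term gave 486, 1721 and, for the interaction, 679, and 88 shared by all tissues against 26; it removes spread between the sets. Numbers 1 to 3 alone, with 3 against 3, gave 0 in each tissue with limma (963, 1588 and 1564 at an unadjusted p under 0.05), and numbers 4 to 8 gave 454, 1399 and 364. The lobe score with the set term gave 1188 in pituitary, 529 of them among the 534. The lymphocyte score with the set term gave 345 in mammary gland, 284 of them among the 668. All 48 libraries in 1 fit, which shares the spread of the tissues, gave 59, 815 and 2311, and a minimum absolute log2 change of 1 gave 8, 42 and 104. Lists past the threshold were 7, 6 and 8; with an estimated correlation, with or without the set term, they were 3, 0 and 0 (6, 3 and 3 at an unadjusted p under 0.05 without the term). With fry they were 10 in pituitary and 3 in mammary gland; the cause was not tested.

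With the replicate number as a block, hypothalamus had 281 and pituitary 1213 genes, and 53 were shared by all tissues, while in mammary gland the calls of Pck1 and Mvk ended (adjusted p = 0.0508 and 0.0637). The numbers were not shown to pair control with heat: the library of the same number was the best match in 2, 1 and 2 of 8 cases. Correlations of same-numbered control and heat libraries ran from 0.07 to 0.7, −0.02 to 0.5 and −0.1 to 0.34 in hypothalamus, pituitary and mammary gland. The number within a treatment as a block across tissues gave 548 genes for the interaction.

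With 1 library left out, hypothalamus had 43 to 132 genes, pituitary 331 to 910 and mammary gland 413 to 759, with 6 to 11, 4 to 8 and 5 to 9 lists. Counts moved over 1.5 times without hypothalamus control replicates 4 (54), 5 (43), 7 (44) and 8 (60) and heat replicates 4 (59), 5 (60) and 8 (63). They did so without pituitary control replicate 5 (331) and heat replicates 3 (910), 4 (336) and 5 (343), and mammary heat replicates 4 (413) and 5 (442). Lists did so without hypothalamus control replicate 5 (11) and mammary control replicate 2 (5) and heat replicate 6 (5). Calls of Opalin and Per2 in hypothalamus were lost without control replicates 5 or 7 or heat replicates 4, 5 or 8, and Opalin also without control replicate 8. Egr1 was lost without control replicates 5 or 7 or heat replicates 5 or 8. Mcm3 in pituitary was lost without control replicates 2, 4, 5 or 8 or heat replicates 5 or 6, and Cmtm2a in mammary gland without control replicates 1, 2 or 8 or heat replicates 4 or 8. For these genes adjusted p in the fits that lost the call reached at most 0.0582. The milk protein share differed by −2.66 to −1.01 points. In mammary gland 3 fragments in a 1 kb gene corresponded to up to 0.6 FPKM, the highest floor of the tissues. This floor is set by the FPKM denominator, which did not follow library depth.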

Other observations

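Bcl6, Plin2 and Fkbp5 were chosen after their values were seen, and the test of a shared dam was chosen after the result was seen. Bcl6, a transcriptional repressor, had the smallest adjusted p for a difference between tissues (3.22e-08): it went from 1.46 ± 0.36 to 10.2 ± 4.04 FPKM in mammary gland (SD, n = 8; log2 change 2.12, above the highest control in 8 of 8), and its change exceeded that of hypothalamus by 1.77 ± 0.19. Plin2, a lipid droplet coat gene, rose by 0.70 in pituitary and had −0.32 in mammary gland (adjusted p = 0.101), a difference of −1.02 ± 0.14. P4ha1, a collagen prolyl hydroxylase gene, rose by 0.69, 0.90 and 1.97 in hypothalamus, pituitary and mammary gland. Fkbp5, a glucocorticoid receptor chaperone gene, had 0.32 and 0.25 in hypothalamus and pituitary, neither past the threshold, and rose by 0.87 in mammary gland.

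The heat change differed between pituitary and hypothalamus for Rnd3 (−1.05, adjusted p = 0.00244) and Nmt2 (0.75, adjusted p = 0.0168). Prkab1, Cirbp and Lcmt2 fell in hypothalamus and pituitary, and Nrde2, Wdr73, Prkab1, Heatr3 and Lcmt2 in hypothalamus and mammary gland. Rasd1 and Gpr146 passed in opposite directions in pituitary and mammary gland. Apart from Cirbp, Lcmt2 and Rasd1, these genes were chosen after their values were seen.

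Mitochondrially encoded genes held 8.27 ± 2.27% of summed FPKM in control and 7.90 ± 1.81% in heat hypothalamus (SD, n = 8; exact permutation p = 0.707). The shares were 4.42 ± 0.83% and 3.72 ± 0.75% in pituitary (SD, n = 8; exact permutation p = 0.0949, 0.425 adjusted over 6 shares) and 3.61 ± 0.25% and 3.30 ± 0.65% in mammary gland (SD, n = 8; exact permutation p = 0.227).

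Same-numbered libraries of 1 treatment resembled each other across tissues. After treatment and library set were removed, the best match had the same number for 14, 13 and 16 of 16 libraries in the 3 pairs of tissues. Permutation p was at most 3e-05, and 1e-05 in 1 pair, the smallest that 100000 resamples give. This is consistent with 1 dam having given the 3 libraries of a number; shared handling could give the same and was not tested apart.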
